A study of Mus musculus with 6 samples.

How the data were processed

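RNA from the whole oviduct of pregnant mice at gestational day 3 was sequenced in 6 libraries, 3 from animals labelled Mettl3 f/f and 3 from animals labelled Mettl3 d/d. Mettl3 encodes the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. The f/f label is the usual notation for a gene flanked by loxP sites and d/d for the deleted form; neither the deleted exons nor the Cre driver are given in the sources used here. RNA was extracted with TRIzol and libraries were made with the TruSeq RNA kit, per the labels' protocols.

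The deposited values were read as FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, one per Ensembl gene and library. This unit is an inference: Cufflinks 2.2.1 is named per the submitters' processing notes, and the deposited values are decimals whose library totals differ, from 588802 to 751618. HISAT2 2.2.1 and the genome builds mm9 and mm10 are also named per the submitters' processing notes, with no role given for either build. The annotation, the filters and the strand setting are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart, and reads of near-identical paralogs and pseudogenes can be split between them. Each of the 6 deposited tables held the same 55483 features, of which 55223 (99.5%) had their Ensembl identifier in GENCODE release M21, used here for coordinates (GRCm38) and gene classes. No pair of libraries held identical values (0 pairs).

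No read totals are in the tables. In single-transcript genes longer than 1500 nt with FPKM under 0.1, the FPKM multiplied by the transcript length less 255 nt fell on a common lowest step, taken as the value of 1 fragment. Between 94.5% and 98.1% of the 295 to 384 genes used per library lay within 1% of that step, which implied 16600000 to 17800000 fragments per library. Other values were not whole multiples that could be turned back into counts, so no count model was used. An exact 0 in these tables can be a failed estimate. There were 4 features above 1000 FPKM in at least 1 library and listed at 0 in another, and the longest of them was 162 nt. Genes at 0 are therefore described as listed at 0, with each library's value and no fold change.

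Rows that shared a symbol (114 symbols) were summed. Features with a mean FPKM of at least 1 over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with genotype as the only term, two-sided, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 changes are differences of mean log2(FPKM + 1), d/d minus f/f, and understate the change of low genes. Folds are ratios of group mean FPKM. For Mettl3 an exact permutation test was added. The labels do not say that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

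A total of 29 gene lists covering the m6A machinery, cell types, steroid response, immune response, stress, transport and contractility were fixed before the data were examined, as were the test, the filter and the rule for the genes named. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists. The fry test was run for the net direction of each list and for change in either direction, which compares a list with no change and not with other genes. The genes named were Mettl3, the 12 with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap (leaving out model names, small RNAs and immune receptor segments), and up to 4 members of each list past the threshold by size of change, or the 2 most abundant members where none passed. Of the genes this rule names, 2 are not reported here. Of genes outside it, those that complete a count of 5 or fewer are named with it; Tox4, Sall2, Mettl14, Pgr, Esr1, Fkbp5, Calca, Ovgp1, Hoxa10, Foxj1, Cd163, Myh11, Cyp11a1 and the gene families of the closing section were chosen after their values were seen.

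The fit was tested on simulated data with the residual spread of these 15438 features and 200 changed genes in each of 10 simulations. It recovered 2.83% of genes changed by 0.5 on the log2 scale, 49.9% of those changed by 1 and 86.8% of those changed by 2, with 6.23% false calls. A list of 20 genes shifted by 0.5 was called in 10 of 10 simulations and an unshifted one in 0 of 10 with camera at its unadjusted p under 0.05. The simulated genes varied independently of each other. The real lists did not, with estimated correlations such as 0.946 (multiciliated) and 0.351 (macrophage and myeloid). The simulation therefore does not measure false list calls in these data. The alternatives fixed in advance were a pseudocount of 0.1, no filter, quantile normalization, trimmed mean of M values (TMM) scaling written in R for the FPKM, no variance trend, the highest row per symbol, the replicate number as a block, each library left out in turn, a minimum of 2-fold and the estimated correlation. Another 4 were chosen after seeing the data: leaving out f/f replicate 1 and d/d replicate 1 together, protein-coding nuclear genes rescaled to a common total, and Hoxa10 or the mean of the multiciliated list as a covariate. Tables were built with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.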

Results

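The oviduct carries the early embryo to the uterus, and on gestational day 3 of mouse pregnancy it does so under ovarian steroids. To ask how its transcripts differ when Mettl3 is deleted, whole oviducts labelled Mettl3 f/f (n = 3 libraries) were compared with whole oviducts labelled Mettl3 d/d (n = 3 libraries). The steps of the low FPKM values implied 17800000, 17800000 and 17100000 fragments for f/f replicates 1 to 3 and 17200000, 16600000 and 16900000 for d/d replicates 1 to 3, and between 21085 and 22211 features per library had an FPKM above 0. Features encoded by mitochondrial DNA held 4.59% ± 1.05 (SD, n = 3) of all FPKM in f/f and 7.65% ± 1.78 (SD, n = 3) in d/d. The 10 most abundant features held 13.1% ± 2.02 (SD, n = 3) and 19.7% ± 2.93 (SD, n = 3). Pseudogenes held 24.4% ± 2.41 (SD, n = 3) and 28.5% ± 3.77 (SD, n = 3), a share that short features with very high FPKM can raise. Pearson correlations of log2(FPKM + 1) across genes ran from 0.935 to 0.964 within groups and from 0.897 to 0.920 between groups. The first principal component held 45% of the variance and separated the groups. The second held 22.3%, and f/f replicate 1 (41.4) and d/d replicate 1 (-30.3) lay at its ends.

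Mettl3 (ENSMUSG00000022160; chromosome 14, 52294841 to 52305128 on the minus strand of GRCm38) was not lower in the libraries labelled d/d. Its FPKM was 11.8, 12.1 and 13.2 in f/f replicates 1 to 3 and 19.8, 20.3 and 24.5 in d/d replicates 1 to 3. The means were 12.4 ± 0.736 (SD, n = 3) and 21.5 ± 2.59 (SD, n = 3), a 1.74-fold higher level in the libraries labelled d/d. The log2 change was 0.75 (SE 0.12, limma adjusted p = 0.0145), and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows. The call missed the threshold without f/f replicate 2 (log2 change 0.74, limma adjusted p = 0.0685) and with the replicate number as a block (limma adjusted p = 0.0559). A value per gene cannot show whether an exon is missing, so this check did not verify the genotype labels, and every direction below rests on them. The 3' ends of Mettl3 and of Tox4 (chromosome 14, 52279146 to 52296401, plus strand) overlap, and Tox4 was at 16.7 ± 0.942 FPKM (SD, n = 3) in f/f and 15.6 ± 0.791 (SD, n = 3) in d/d, a difference within the test's error (limma adjusted p = 0.608).

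**Figure D1:**
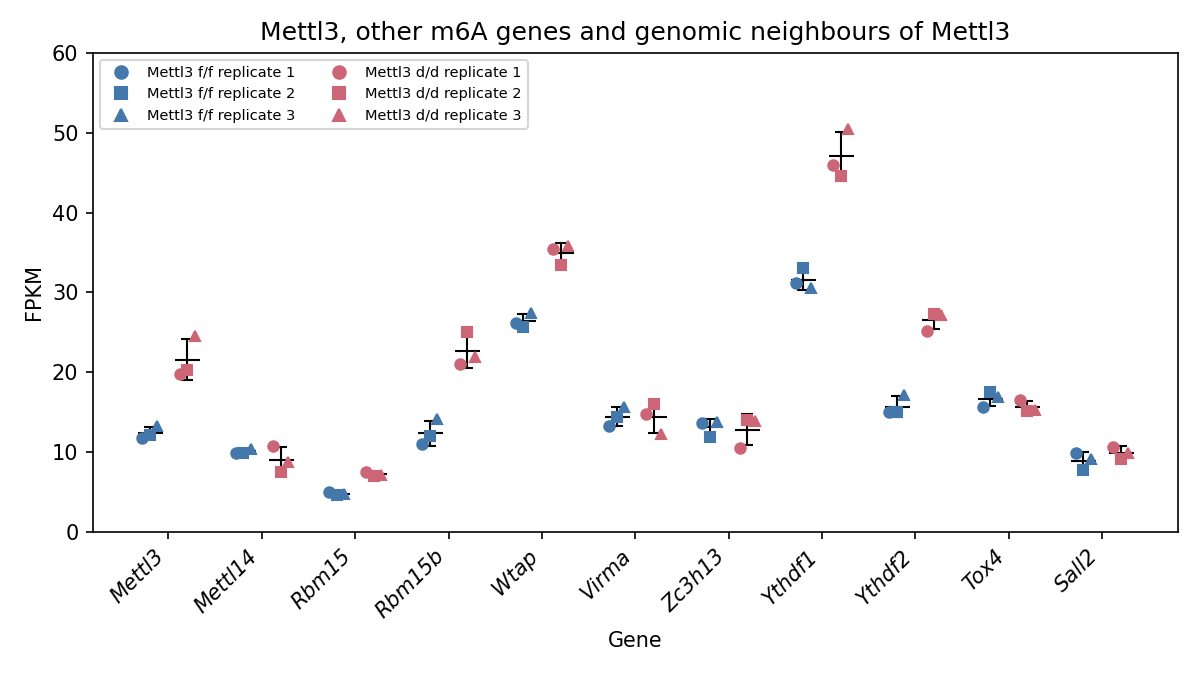
FPKM (vertical axis) of Mettl3, other m6A genes and the genomic neighbours Tox4 and Sall2 (horizontal axis) in each library, with blue symbols for f/f, red for d/d, a shape per replicate number, and bars for the mean and SD of 3 libraries. The 3 d/d values of Mettl3 lie between 19.8 and 24.5 and the 3 f/f values between 11.8 and 13.2.

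Some other genes of the m6A pathway were also higher in the libraries labelled d/d. Of 9 measured members of the writer complex, 4 rose and 0 fell: Mettl3, Rbm15b (1.83-fold), Rbm15 (1.52-fold) and Wtap (1.32-fold), the last being the adaptor that holds the catalytic pair. Rbm15b went from 12.4 ± 1.57 to 22.7 ± 2.11 FPKM (SD, n = 3 each; limma adjusted p = 0.0140). Mettl14, the partner of Mettl3 in the catalytic core, was at 10.04 ± 0.247 in f/f and 8.998 ± 1.65 in d/d (SD, n = 3 each; limma adjusted p = 0.514). Adjusted over the list alone, 5 members rose and 0 fell. The list was called higher by camera (adjusted p = 0.0203), and it was not with the estimated correlation (adjusted p = 0.641 with an estimated correlation). The number of writer genes that rose was 0 without f/f replicate 2, 3 without f/f replicate 1 and 2 without any other single library. Without f/f replicate 1 and d/d replicate 1 the camera call was lost (adjusted p = 0.0563). Among 10 measured erasers and readers, the m6A-binding proteins Ythdf2 (1.69-fold) and Ythdf1 (1.49-fold) rose and 0 fell, and 2 rose adjusted over the list alone. Of these readers 0 rose without f/f replicate 2, and 1 without f/f replicate 3 or d/d replicate 3. That list was not called (camera adjusted p = 0.606), with a median log2 change of -0.0043 and a mean of 0.04.

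The genes with the largest rises in the libraries labelled d/d had varied functions. Pigr, the receptor that carries polymeric immunoglobulin across epithelia, went from 4.08 ± 1.56 to 74.3 ± 11.3 FPKM (SD, n = 3 each; log2 change 3.93, SE 0.26, limma adjusted p = 0.0026). Anpep, a cell-surface aminopeptidase, rose 11.04-fold, from 87.1 ± 16.7 to 962 ± 236 FPKM (SD, n = 3 each). Hgfac, which encodes a serine protease that activates hepatocyte growth factor, rose 16.6-fold and Gtf2a1l, a general transcription factor subunit best known from testis, 52.9-fold, from 0.187 ± 0.0884 to 9.91 ± 0.774 FPKM (SD, n = 3 each). The retinoic acid-binding protein gene Crabp2 (26.3-fold; 49.8-fold without f/f replicate 2), the mucin Muc20 (17.1-fold), the chemokine Cxcl17 (8.61-fold), Sprr2f (17.9-fold), the secreted phosphoprotein Spp1 (13.7-fold) and Reg1 (9.91-fold) were also among the largest rises, with Saa3, an acute-phase gene. Saa3 varied widely among d/d libraries, at 96.5, 34.1 and 5.53 FPKM for replicates 1 to 3, against 0.596 and 0.587 in f/f replicates 1 and 2 and a value listed at 0 in f/f replicate 3.

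The genes with the largest falls were varied as well. Coch fell from 86.6 ± 52.3 to 1.13 ± 1.02 FPKM (SD, n = 3 each; log2 change -5.19, SE 0.61, limma adjusted p = 0.00845), a 76.9-fold fall that was 160-fold without d/d replicate 1. Npl, an enzyme of sialic acid breakdown, was 43.2-fold lower, Acbd7 71.7-fold (128-fold without d/d replicate 2), Cwh43 43.1-fold, the amino acid transporter Slc6a14 67.4-fold and the endocytic receptor Lrp2 92.3-fold (296-fold without d/d replicate 1). Wfdc15b, of the whey acidic protein family, went from 215 ± 40.2 to 14.4 ± 6.41 FPKM (SD, n = 3 each), the calcium-binding gene S100g was 15.8-fold lower, the glutathione transferase Gstm7 12.7-fold and Ecrg4 11.4-fold. Ano2, a calcium-activated chloride channel, was at 3.42, 22.5 and 24.5 FPKM in f/f replicates 1 to 3, at 0.0474 in d/d replicate 1 and listed at 0 in d/d replicates 2 and 3. Cyp2j11 was likewise listed at 0 in d/d replicates 2 and 3 and at 0.0700 in d/d replicate 1, against 2.65, 23.8 and 22.9 FPKM in f/f. In f/f replicate 1 several of these genes were far below the other f/f libraries: Coch was at 26.6 FPKM there against 123 and 110, and Npl at 27.5 against 178 and 160. Of the genes that fell, f/f replicate 1 was the lowest f/f library in 363 (47.3%, where chance gives 33.3%), and in 35 of the 50 with the largest fall.

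In all, 1701 of 15438 features passed the threshold (limma, Benjamini-Hochberg), 933 higher and 768 lower in the libraries labelled d/d, and 4562 had an unadjusted p under 0.05. The 3 d/d and 3 f/f values did not overlap in any of the 1701, nor in 35.6% of all features tested, where chance gives 10%. At a minimum of 2-fold on the log2(FPKM + 1) scale, 351 were higher and 346 lower. The count changed when single libraries were left out. It was 312 without f/f replicate 2, 524 without f/f replicate 3, 895, 646 and 684 without d/d replicates 1, 2 and 3, and 1798 without f/f replicate 1. These fits keep 3 residual degrees of freedom in place of 4, which lowers power, so a lost call need not mean a smaller change. Without f/f replicate 2 the log2 change of Mettl3 was 0.74 against 0.75, and the median of the cell cycle list 0.90 against 0.92. Of the 76 genes named by rule that passed, 27 kept the call without f/f replicate 2, 40 without f/f replicate 3, 45, 43 and 43 without d/d replicates 1, 2 and 3, and 67 without f/f replicate 1. Without f/f replicate 1 and d/d replicate 1, an alternative chosen after seeing the data, it was 1637, of which 1048 were among the 1701.

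**Figure D2:**
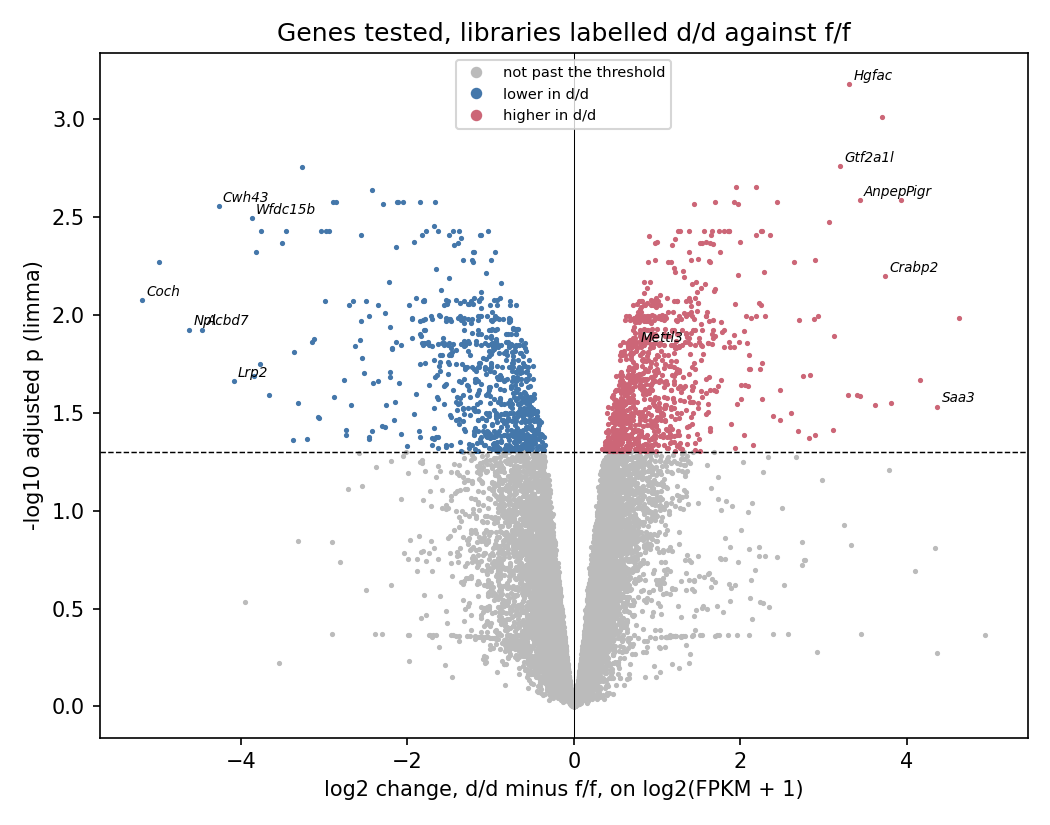
Log2 change on the log2(FPKM + 1) scale (horizontal axis) against -log10 of the limma adjusted p (vertical axis) for 15438 features, red for the 933 higher and blue for the 768 lower in the libraries labelled d/d, grey for the rest, with the dashed line at the threshold of 0.05. Mettl3 lies among the higher genes, at a log2 change of 0.75.

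Several genes of the steroid receptor and progesterone list were lower in the libraries labelled d/d, while the transcript of the progesterone receptor was at a like level. Whether other steroid hormones act on these genes was not tested. Il13ra2 was at 7.47, 5.12 and 7.21 FPKM in f/f replicates 1 to 3, at 0.0456 in d/d replicate 1 and listed at 0 in d/d replicates 2 and 3. Zbtb16, a transcription factor gene induced by progesterone, was 12.04-fold lower, from 15.9 ± 3.30 to 1.32 ± 0.405 FPKM (SD, n = 3 each; log2 change -2.86, SE 0.21, limma adjusted p = 0.00267). Ihh, an epithelial signal downstream of the receptor in the uterus, was 5.35-fold lower and the immunophilin gene Fkbp5 5.18-fold lower. Pgr itself was at 41.0 ± 4.94 FPKM in f/f and 40.2 ± 5.57 in d/d (SD, n = 3 each; log2 change -0.03, 95% interval from -0.37 to 0.31, limma adjusted p = 0.910). Of 21 measured members of the steroid receptor and progesterone list, 0 rose and 6 fell (Lrp2, Il13ra2, Zbtb16, Ihh, Fkbp5 and Calca), also 0 and 6 adjusted over the list alone. The list was called lower by camera (adjusted p = 0.0133; adjusted p = 0.641 with an estimated correlation), with a median log2 change of -0.24 and a mean of -0.79. The number that fell was 2 without f/f replicate 2, f/f replicate 3, d/d replicate 2 or d/d replicate 3, 3 without d/d replicate 1 and 8 without f/f replicate 1. Hoxa10, a gene of the uterine end of the tract, was lower in f/f replicate 1 and d/d replicate 1 than in the rest of their groups, at 3.48, 26.5 and 25.1 FPKM in f/f and 4.24, 9.47 and 12.4 in d/d. Lrp2 and Ihh were lowest among f/f libraries in replicate 1. This did not hold in d/d, where replicates 1 to 3 were at 0.747, 0.106 and 0.0893 FPKM for Lrp2 and 7.69, 4.27 and 9.65 for Ihh.

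Several estrogen-responsive secretory genes rose. Ltf, which encodes lactotransferrin, rose 4.13-fold to 2012 ± 510 FPKM (SD, n = 3), Lcn2 7.15-fold to 513 ± 250 (SD, n = 3), complement C3 4.26-fold to 777 ± 286 (SD, n = 3), and Muc1 2.94-fold. Cyp26a1, a retinoic acid-degrading enzyme gene placed in the same list, was 4.38-fold lower. Of 16 measured members of the estrogen response list, 4 rose and 1 fell, and 6 rose and 1 fell adjusted over the list alone. The number that rose was 1 without f/f replicate 2 and 2 without f/f replicate 3, d/d replicate 2 or d/d replicate 3. Esr1 was at 139 ± 1.89 FPKM in f/f and 154 ± 15.01 in d/d (SD, n = 3 each; limma adjusted p = 0.408). Camera called the list higher (adjusted p = 0.0415; adjusted p = 0.641 with an estimated correlation), and it lost the call without f/f replicate 2 (adjusted p = 0.0769), f/f replicate 3 (0.0597) or d/d replicate 2 (0.105). Ltf, Lcn2 and Muc1 also stand in the list of oviduct secretory epithelium, and Pgr and Esr1 in both steroid lists.

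**Figure D3:**
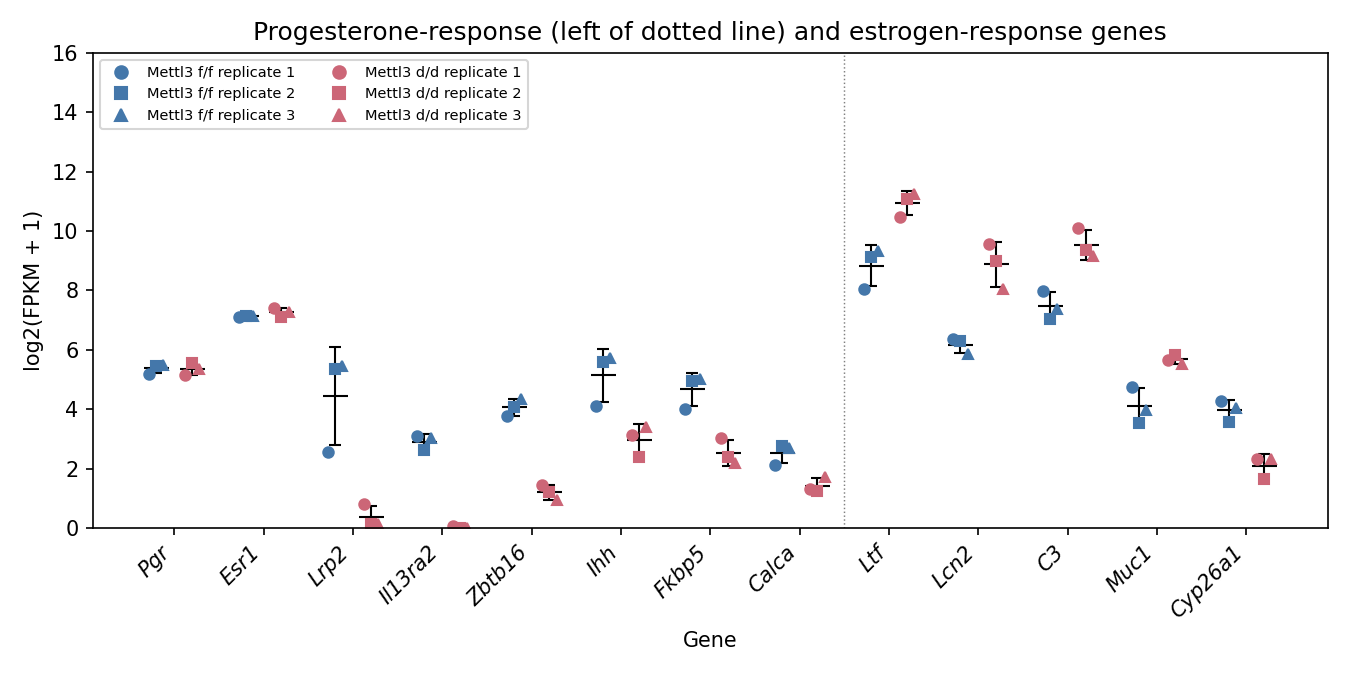
log2(FPKM + 1) (vertical axis) of progesterone-response genes and receptors (left of the dotted line) and estrogen-response genes (right) in each library, with blue for f/f, red for d/d, a shape per replicate number, and bars for the mean and SD of 3 libraries, drawn where no value is 0. Pgr overlaps between groups, while the d/d values of Zbtb16 lie below and those of Ltf above the f/f values.

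Macrophage and myeloid genes rose together. Of 14 measured members 11 rose and 0 fell, and 13 rose and 1 (Cd163) fell adjusted over the list alone, with a median log2 change of 1.26. The number that rose over all genes was 4 without f/f replicate 2, 5 without f/f replicate 3 or d/d replicate 2, 8 without d/d replicate 1 or 3, and 11 without f/f replicate 1. Lyz2, which encodes lysozyme, went from 138 ± 8.34 to 466 ± 79.8 FPKM (SD, n = 3 each; limma adjusted p = 0.0037), the complement genes C1qb and C1qc rose 3.26-fold and 3.07-fold, and the Fc receptor chain Fcer1g 3.23-fold. Cd163, a scavenger receptor of resident macrophages, was at 2.74 ± 0.749 FPKM in f/f and 1.46 ± 0.218 in d/d (SD, n = 3 each; limma adjusted p = 0.127 over all genes). Camera called the list at an adjusted p of 2.4e-08 (adjusted p = 0.641 with an estimated correlation). The lymphocyte list was called higher (8 measured, 1 rose and 0 fell, 3 and 0 adjusted over the list alone; camera adjusted p = 0.0477; adjusted p = 0.722 with an estimated correlation), and its riser was the B cell receptor chain Cd79b (2.65-fold). The inflammatory and acute-phase list was called higher (11 measured; camera adjusted p = 0.0494; adjusted p = 0.693 with an estimated correlation), with Saa3 and the monocyte chemokine Ccl2 (6.41-fold) rising and the neutrophil growth factor Csf3 3.40-fold lower, and 5 rising and 1 falling adjusted over the list alone. Both calls were lost without f/f replicate 3 (adjusted p = 0.0888 for lymphocytes and 0.0925 for the inflammatory list) or without d/d replicate 2 (0.123 for both). The lymphocyte call was also lost without f/f replicate 2 (0.103), and the inflammatory call without f/f replicate 1 (0.0727) or without it and d/d replicate 1 (0.0717). TMM scaling also ended both calls (0.0527 each), as did Hoxa10 as a covariate (0.1225 and 0.115). Rescaling to protein-coding nuclear genes ended the lymphocyte call (0.103) and a pseudocount of 0.1 the inflammatory one (0.0533). Cd79b kept its call without f/f replicate 1 and missed the threshold without any other single library. In the inflammatory list 0 rose without d/d replicate 2, and 1 rose and 0 fell without f/f replicate 2 or f/f replicate 3. In the neutrophil list (9 measured; camera adjusted p = 0.420) Csf3r rose 3.79-fold, and 1 rose and 0 fell adjusted over the list alone. The number that rose there was 3 without f/f replicate 1, and 0 without f/f replicate 2, f/f replicate 3, d/d replicate 2 or d/d replicate 3.

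Proliferation genes were higher in the libraries labelled d/d. Of 18 measured cell cycle genes 7 rose and 0 fell, and 15 rose adjusted over the list alone. The number that rose over all genes was 0 without f/f replicate 2, 1 without f/f replicate 3, d/d replicate 1 or d/d replicate 2, 6 without d/d replicate 3 and 8 without f/f replicate 1. The survivin gene Birc5 rose 4.51-fold, from 2.00 ± 1.19 to 9.04 ± 2.97 FPKM (SD, n = 3 each; limma adjusted p = 0.0215), cyclin B2 (Ccnb2) 4.32-fold, the replication helicase subunit Mcm3 2.53-fold and Cdk1 2.38-fold. Leaving out f/f replicate 1, the highest f/f library for both, gave 6.82-fold for Birc5 and 7.13-fold for Ccnb2. The median log2 change was 0.92, and camera called the list at an adjusted p of 5.8e-07 (adjusted p = 0.675 with an estimated correlation).

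Ciliated cell, interferon and mitochondrial genes varied among the libraries of a group as well as between groups. Of 24 measured multiciliated genes 0 rose and 1 fell (Rfx2, a transcription factor gene of ciliated cells, 2.15-fold lower), and 0 of either kind passed adjusted over the list alone. Foxj1, the master regulator of motile cilia, was at 93.8, 46.5 and 27.9 FPKM in f/f replicates 1 to 3 and 11.9, 56.1 and 32.9 in d/d replicates 1 to 3. The list was called lower by camera (adjusted p = 0.0118; adjusted p = 0.757 with an estimated correlation), with a median log2 change of -0.83. The call was lost without f/f replicate 1 (median -0.34, adjusted p = 0.239) or d/d replicate 1 (-0.23, 0.313), and without both the direction turned (0.27, 0.401). Rfx2 passed without d/d replicate 2 and missed the threshold without any other single library. The type I interferon list was called higher (25 measured, 0 rose and 0 fell at either adjustment; camera adjusted p = 0.0146; adjusted p = 0.757 with an estimated correlation). Its 2 most abundant members, Bst2 and Oasl2, were at 228 ± 41.5 and 104 ± 77.5 FPKM in f/f and 350 ± 39.8 and 97.1 ± 11.7 in d/d (SD, n = 3 each). The interferon call was lost without f/f replicate 2 (adjusted p = 0.103), f/f replicate 3 (0.158) or d/d replicate 1 (0.0774), and with Hoxa10 as a covariate (0.151). When f/f replicate 1 was left out, 11 of the 25 rose (camera adjusted p = 8.7e-09); the mean log2 level of the list was 4.82 in that library and 3.67 and 3.68 in the other f/f libraries. Among 9 measured mitochondrially encoded genes mt-Nd2 (3.00-fold) and mt-Nd1 (2.45-fold) rose and 0 fell, 3 rose adjusted over the list alone, and camera called the list higher (adjusted p = 0.0105; adjusted p = 0.722 with an estimated correlation). Quantile normalization ended the mitochondrial call (median log2 change 0.53, adjusted p = 0.083), and 0 members rose when any single library was left out.

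Camera called none of the remaining lists on the deposited scale. Among 15 secretory epithelium genes, 4 rose and Itih5 fell (2.76-fold lower), 4 and 3 adjusted over the list alone (camera adjusted p = 0.837; median log2 change -0.20, mean 0.20). Ovgp1, the oviductal glycoprotein, was at 4993 ± 714 FPKM in f/f and 4013 ± 1235 in d/d (SD, n = 3 each; limma adjusted p = 0.479). Of 14 pan-epithelial genes, Prom1 (1.92-fold), Elf3 (1.63-fold), Epcam (1.52-fold) and Cdh1 rose and the keratin Krt18 fell (1.46-fold lower), 5 and 4 adjusted over the list alone (camera adjusted p = 0.683). Of 15 stromal genes, Mfap5 (2.10-fold), Lum and Postn rose and Fn1 (2.18-fold lower), Pi16 (2.45-fold lower) and Pdgfra (1.87-fold lower) fell, 3 and 4 adjusted over the list alone (camera adjusted p = 0.840). Of 18 smooth muscle genes, 0 rose and 3 fell at either adjustment: Des (2.57-fold lower), Synpo2 (2.32-fold lower) and Hspb7 (1.37-fold lower). Smooth muscle was not called on the deposited scale (camera adjusted p = 0.0807) and was called lower with quantile normalization (0.0295), without f/f replicate 1 (1.35e-04), d/d replicate 1 (0.029) or both (7.96e-07) and with the multiciliated mean as a covariate (4.45e-04), and Myh11, the smooth muscle myosin gene, was at 232, 580 and 624 FPKM in f/f replicates 1 to 3. Of 12 endothelial genes Vwf rose (2.17-fold) at either adjustment (camera adjusted p = 0.420). No endothelial, pan-epithelial or smooth muscle gene passed without f/f replicate 2, and 0 stromal genes rose and 1 fell. Without f/f replicate 3 or d/d replicate 3, 0 pan-epithelial and 0 stromal genes rose, and without d/d replicate 1 or 2, 1 pan-epithelial gene rose. In smooth muscle 4 fell when f/f replicate 1 was left out and 0 when any other library was. Secretory genes that rose numbered 1 without f/f replicate 2 or d/d replicate 3 and 2 without f/f replicate 3 or d/d replicate 2.

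Some genes of transport and stress changed. Of 25 contractility and embryo transport genes, the adrenergic receptor Adra2a rose 3.06-fold, and the prostaglandin E receptor Ptger2 (3.23-fold lower) and adrenomedullin (Adm, 2.65-fold lower) fell, 1 and 2 adjusted over the list alone (camera adjusted p = 0.729). Of 14 ion and water transport genes, 0 rose and 2 fell, among them the chloride channel Ano1 at 2.19-fold lower, and 0 and 2 adjusted over the list alone (camera adjusted p = 0.693, direction lower, against a median log2 change of 0.11 and a mean of 0.03). Of 17 p53 targets Aen rose 1.62-fold and Sesn1 was 1.68-fold lower, 2 and 2 adjusted over the list alone (camera adjusted p = 0.683). Of 15 stress-response genes Trib3 rose 5.43-fold and Creld2 was 1.94-fold lower, 1 and 2 adjusted over the list alone (camera adjusted p = 0.833). Of 15 immediate early genes Dusp1 fell (1.94-fold lower), 0 and 1 adjusted over the list alone, and the list missed the threshold (camera adjusted p = 0.0546) but was called lower without f/f replicate 1 (0.0215), f/f replicate 2 (0.037) or d/d replicate 2 (0.0285). It was also called lower with no filter (0.02735), quantile normalization (0.0486), the multiciliated mean as a covariate (0.0279) and without f/f replicate 1 and d/d replicate 1 together (0.0381). In these 5 lists Adm alone passed without f/f replicate 2. Aen missed the threshold whichever library was left out, Sesn1 and Creld2 passed where it was f/f replicate 1, and Dusp1 where it was f/f replicate 1 or f/f replicate 3.

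Markers of other tissues gave 1 call among their members, Sprr2f in the uterine list (5 measured, 1 and 0 adjusted over the list alone; camera adjusted p = 0.221). No member passed at either adjustment in the adipocyte (7 measured; camera adjusted p = 0.152), mesothelial (8; 0.1997), red blood cell (5; 0.221), ovarian somatic cell (5; 0.805) and glial and neuronal (6; 0.683) lists. Without f/f replicate 2 the adipocyte list was called lower (0.037), as was the mesothelial list without d/d replicate 1 (0.0331) or with Hoxa10 as a covariate (0.0316), and the neutrophil list was called higher without f/f replicate 1 (0.0441). The red blood cell list was called lower without f/f replicate 1 and d/d replicate 1 together (0.0381) and with the multiciliated mean as a covariate (0.036). Wt1 was at 63.7 ± 26.3 FPKM in f/f and 49.2 ± 12.9 in d/d, Hbb-bs at 76.2 ± 16.7 and 42.0 ± 21.8, Foxl2 at 26.2 ± 5.70 and 32.3 ± 1.88, Lipe at 11.6 ± 0.902 and 11.9 ± 2.39, and Ncam1 at 22.0 ± 0.172 and 28.3 ± 6.65 (SD, n = 3 each). The second members named by rule were Msln at 12.5 ± 6.63 and 16.8 ± 11.2, Hba-a1 at 13.9 ± 2.2 and 12.02 ± 4.36, Inha at 3.81 ± 0.900 and 4.91 ± 0.455, and Mbp at 6.10 ± 1.31 and 6.80 ± 1.67 (SD, n = 3 each). Cfd was at 42.5, 1.46 and 8.32 FPKM in f/f replicates 1 to 3, listed at 0 in d/d replicate 1, and at 5.31 and 0.630 in d/d replicates 2 and 3. Msln and Muc16 stand in both the mesothelial and the secretory list, Aqp5 in the estrogen and ion transport lists, and Ptgs2 in the inflammatory and contractility lists. The steroidogenic gene Cyp11a1, chosen after its values were seen, was at 0.725, 0.208 and 13.5 FPKM in f/f replicates 1 to 3. It was at 0.0645 in d/d replicate 2 and listed at 0 in d/d replicates 1 and 3. The mean log2 level of the ovarian list was 3.54 in f/f replicate 3 and from 1.81 to 1.97 in the other libraries. That of the adipocyte list was 3.38 in f/f replicate 1 and from 1.13 to 2.29 in the others. Tests between groups do not show tissue that enters a single library, so other tissue in these f/f libraries stays open. The oocyte and embryo list had 1 measured gene, Gdf9, and was not tested.

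**Figure D4:**
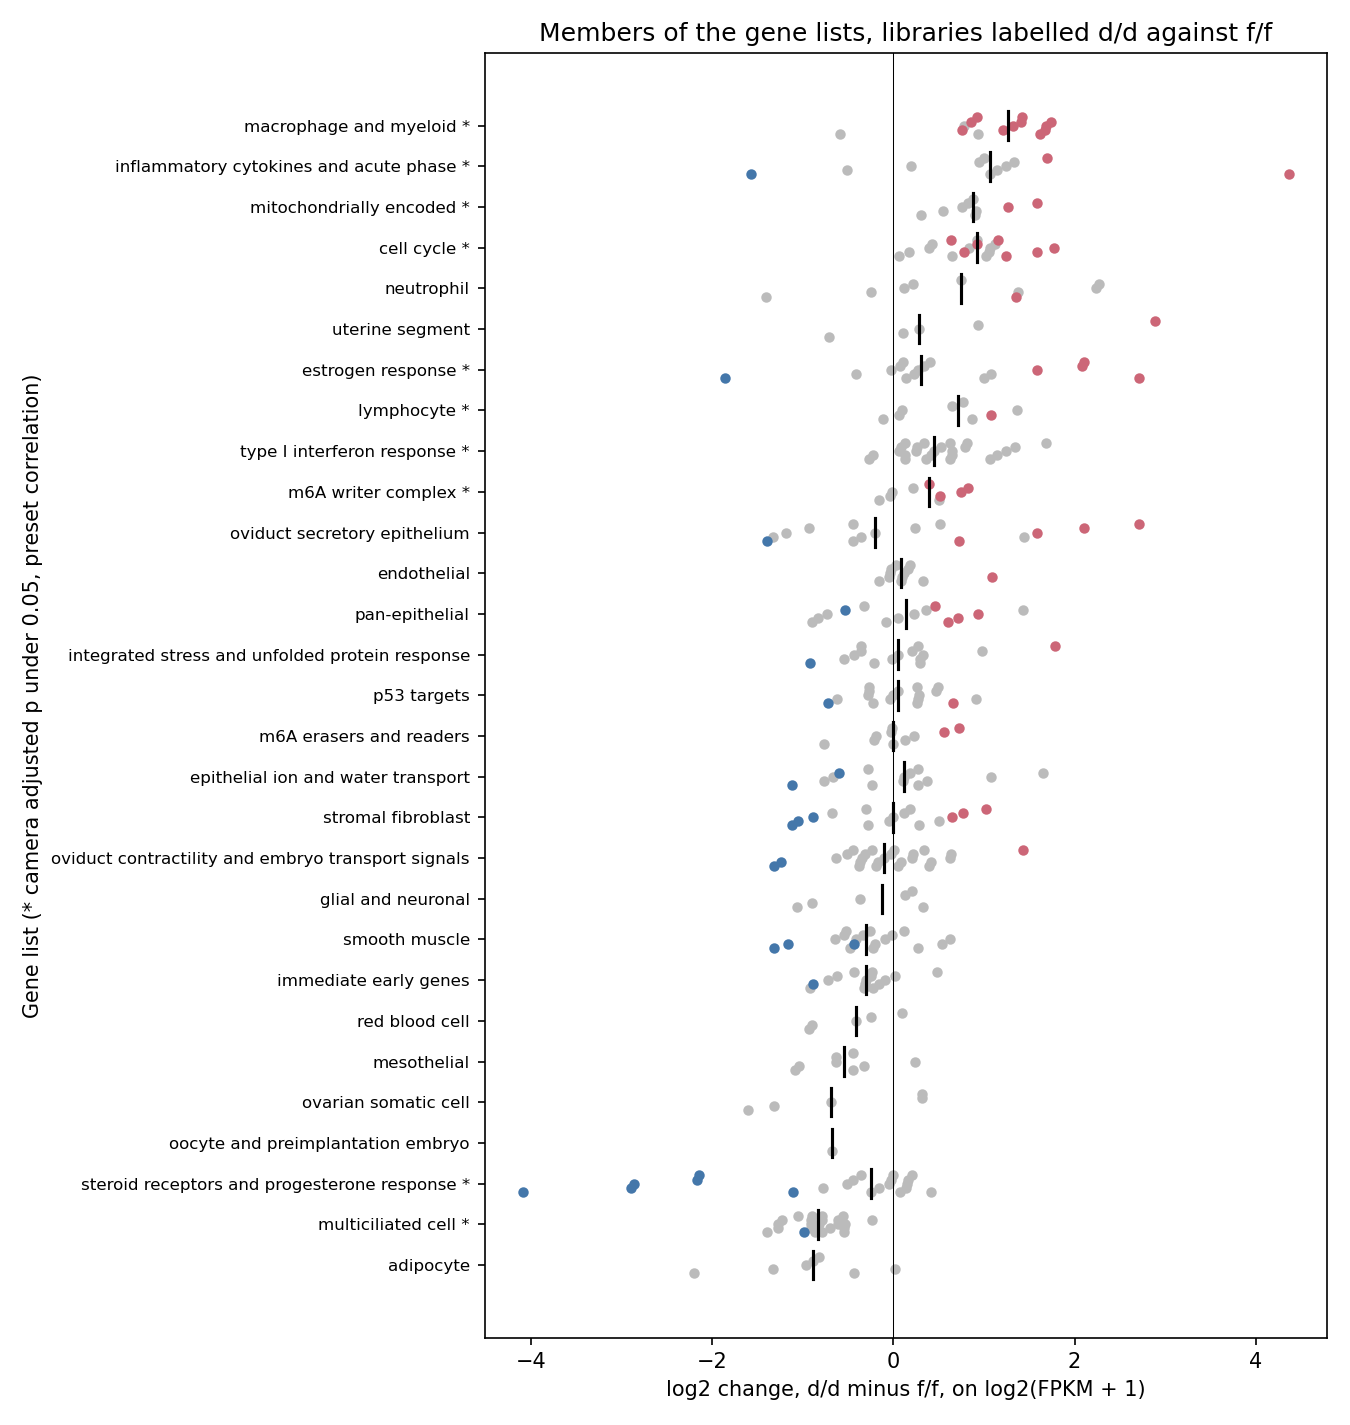
Log2 change on the log2(FPKM + 1) scale (horizontal axis) of each measured member of the 29 gene lists (vertical axis, ordered by mean change), red for members that rose, blue for members that fell, grey for the rest, black bars for medians, and stars for the 10 lists called by camera with the preset correlation. The macrophage and myeloid list has 11 red members and the steroid receptor and progesterone list 6 blue ones; 0 lists were called with the estimated correlation.

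Of the 28 lists tested, camera called 8 higher and 2 lower with the preset correlation and 0 with the estimated one. By fry, 3 lists moved on balance in 1 direction and 18 held changes in either direction. The 3 were the m6A writer, macrophage and progesterone lists (fry adjusted p = 0.0122 each). The cell cycle (fry adjusted p = 0.0675), estrogen (0.0731) and multiciliated (0.455) lists were not among them. Nor were the lymphocyte, inflammatory, interferon and mitochondrial lists.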

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

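The alternatives were planned before the data were examined except for 4 chosen after seeing the data: leaving out f/f replicate 1 and d/d replicate 1 together, protein-coding nuclear genes rescaled, and Hoxa10 or the multiciliated mean as a covariate. The count of changed genes (1701) lay between 1415 and 1819 with a pseudocount of 0.1, quantile normalization, TMM scaling, no variance trend, the highest row per symbol and these 4. With no filter it was 1107 (599 higher, 508 lower), where 26441 features were tested, and at a minimum of 2-fold it was 697 (351 higher, 346 lower). Leaving out single libraries gave 312 to 1798 changed genes (185 to 943 higher, 127 to 855 lower), 6 to 11 called lists and 27 to 67 of the 76 called genes named by rule. The low ends came without f/f replicate 2, and for the lists without f/f replicate 3.

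The log2 change of Mettl3 ran from 0.66 to 0.80 when single libraries were left out, and its adjusted p missed the threshold without f/f replicate 2 (0.0685). With the estimated correlation camera called 0 lists. The multiciliated list had a median log2 change of 0.0226 with its own mean as a covariate, which holds by construction, and 0.27 without f/f replicate 1 and d/d replicate 1; without single libraries it ran from -1.27 to -0.23. The camera calls of the macrophage, cell cycle and progesterone lists held in each alternative except the estimated correlation, while the number of their members past the threshold fell to as few as 4, 0 and 2 when single libraries were left out.

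The labels give both groups replicates 1 to 3 without saying that a number pairs libraries. Libraries with the same number did not deviate together (correlations -0.220, -0.058 and 0.0027), and 0 of 3 pairs were over 0.1 or correlated best with their own number. With the replicate number as a block, which leaves 2 residual degrees of freedom, 276 genes passed (174 higher, 102 lower), with 11 lists, 34 of the 76 named genes, and Mettl3 at a log2 change of 0.75 (adjusted p = 0.0559), and the immediate early list was called lower (0.0419). In the simulations, 2.83% of changes of 0.5 on the log2 scale were recovered. Those simulations held 200 changed genes, where the data gave 1701 calls, and the adjusted threshold is less strict when more genes change. Wtap, for example, was called at a log2 change of 0.39. The simulated share therefore does not give the share of small changes missed here, though some will have been missed.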

Other observations

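Of the tests below, those of uterine-end tissue and of the scaling of the FPKM had their prediction written before their result was seen; the others, and the gene families, were chosen after. The number of changed genes was 1701 for the labelled split of the 6 libraries and at most 2 for the other splits, so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.

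Mettl3 was higher in the libraries labelled d/d. A single mislabelled library is argued against, since 0 libraries lay among the other group in Mettl3 FPKM or correlated best with a library of the other group. A rise of the overlapping gene Tox4 is argued against too, since the upper 95% bound of its log2 change was 0.1544, below 0.375, which is 0.5 times the change of Mettl3. The neighbour Sall2 (chromosome 14, 52311172 to 52328762, minus strand) does not overlap Mettl3. Its reads would count for Mettl3 only if they lay beyond its annotated end. Its log2 change was 0.138 (limma adjusted p = 0.528). The upper 95% bound was 0.4569, above 0.375, so the test cannot decide about Sall2. Exchanged group labels cannot be told apart from a higher level of a transcript lacking an exon, since the change of 0.7498 is a value per gene and the tables hold none per exon.

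Of 21 measured members of the steroid receptor and progesterone list, 6 were lower in the libraries labelled d/d and 15 did not pass. The tests here concern those 6. Less uterine-end tissue is argued against as the whole cause only as far as Hoxa10 tracks that tissue. With Hoxa10 as a covariate the median genotype coefficient of the 6 called members was -2.405, against -2.51 without it, and 6 of 6 stayed past the threshold adjusted over the list alone. Hoxa10 was the only measure used, and its own change was within its error (log2 change -0.71, SE 0.74, limma adjusted p = 0.556). Of 8 measured Hoxa genes, given below as a name family, 5 fell and 0 had a positive log2 change, and only Hoxa10 was used as a covariate. Whether progesterone acts on Hoxa10 itself was not tested. A difference in tissue that Hoxa10 does not follow stays open. Less epithelium as a whole is argued against by the median log2 change of the pan-epithelial list, 0.1419, and less Pgr transcript by the lower 95% bound of Pgr, -0.3701, since each would need a fall past -1.26. In that list 5 members rose and 4 fell adjusted over the list alone. Its median cannot show a smaller share of one part of the epithelium or of the stroma, which stays open. A weaker response to progesterone in the oviduct may explain the pattern, as a hypothesis found on these data. No value here measures that response, and whether other hormones act on these genes was not tested. The level of progesterone was not measured, so a lower level stays open, as do the labels.

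Macrophage and myeloid genes were higher in the libraries labelled d/d. Blood in the tissue is argued against, since the highest of the red blood cell median and the upper 95% bounds of Hbb-bs and Hba-a1 was 0.3799, below the 0.63 it would need. Scaling of the FPKM is argued against, since at least 10 of the 11 called members stayed called under TMM scaling, quantile normalization and rescaling to protein-coding nuclear genes. A larger share of the same macrophages could raise the members that rose. The SD of the log2 changes of the 13 members with a mean FPKM of at least 5 was 1.786 times their typical SE. This unevenness decides nothing, because other cells express some members. Cd163 lay under that level and was left out, with a log2 change of -0.588 and an upper 95% bound of -0.0781. Of those 13 members 0 had an upper 95% bound below 0, so the test cannot decide about a larger share. Cd209a and Retnla, given below, were lower as well, but they lie outside the list. Mean FPKM in d/d was 1.46 for Cd163, 1.12 for Cd209a and 1.19 for Retnla, and no conclusion is drawn from these low genes. Changed expression within the cells and the arrival of other myeloid cells stay open.

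By a hypergeometric test over 370 name families, some families held many changed members. That test takes genes as independent, which genes that change together or share reads are not. The lowest adjusted p was that of the Cd names (17 of 62 rose and 4 fell, hypergeometric adjusted p = 3.42e-05). The C, Csf and Ms names also passed 0.05 for rises and the Aldh names for falls. Of 15 measured Ccl chemokine genes 6 rose (adjusted p = 0.0115, hypergeometric over 370 name families), among them Ccl8, Ccl12 and Ccl28, which went from 3.56 ± 1.42 to 17.9 ± 4.08 FPKM (SD, n = 3 each). Of 7 Gstm glutathione transferase genes 5 fell (adjusted p = 0.00215), where near-identical copies can share reads, and of 8 Hoxa genes 5 fell (adjusted p = 0.00275). The directions of the Ccl, Gstm and Hoxa families held with TMM scaling, quantile normalization and rescaling to protein-coding nuclear genes, where 1 Ccl gene fell. Cd209a (7.26-fold lower) and Retnla (9.31-fold lower, and 20.6-fold without d/d replicate 1) fell. Neither is in the macrophage list, and which cells express them here was not tested. The immunoglobulin constant genes Igha (5.92-fold) and Igkc (4.84-fold) rose, and Jchain missed the threshold (limma adjusted p = 0.0533). The metallothionein and Dcpp families have 3 measured members each, too few for that test, and their genes were chosen after their values were seen. The metallothionein genes Mt1 (4.08-fold lower), Mt2 (6.57-fold lower) and Mt3 (4.44-fold lower, and 7.17-fold without d/d replicate 3), Penk (5.27-fold lower) and the demilune cell protein genes Dcpp1 (21.8-fold lower), Dcpp2 (5.60-fold lower) and Dcpp3 (8.85-fold lower) fell. Leaving out f/f replicate 1 gave 13.7-fold for Dcpp1 and 5.57-fold for Dcpp3, and leaving out d/d replicate 3 gave 8.53-fold for Dcpp2 and 15.6-fold for Dcpp3.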
